A study of Mus musculus with 2 samples.

How the data were processed

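The data came from 1 pooled droplet experiment on T cells from melanoma tumours of C57BL/6J mice. Per the labels' protocols, cells of each tumour were enriched for CD90.2, stained with a hashtag antibody of their own, and 8000 live CD8+ cells per mouse were sorted. The labels describe the cells both as CD3+ T cells and as a CD8+ sort. Cells of a condition were combined after the sort, and hashtagged cells of 8 mice, 4 per condition, went onto 1 lane, so that handling after the sort cannot be separated from treatment. A gene expression library and a hashtag library were made with the Chromium 5′ v2 kit.

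The deposited matrix holds raw UMI counts (unique molecular identifiers, each standing for 1 captured RNA molecule) for 32285 genes and 9 hashtags in 16969 barcodes. Per the file headers it was written by Cell Ranger 4.0.0, and the submitters' processing notes name the build GRCm38; the annotation release and any further filter by the authors are not given in the sources used here. The gene counts total 64359313 UMIs, from 500 to 51956 per barcode, and 13542 genes had no UMI. The hashtag names in the deposited feature list give treatment (LR or PBS) and mouse number, and mice were grouped from these names alone. LR was read as the L. reuteri treatment named in the labels, since the other hashtags are named PBS. Mouse numbers differ between the groups and pair no mice.

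Barcodes with at least 500 genes and at most 10% mitochondrial UMIs were kept, 14474 in all. A hashtag was called above a threshold between the components of a Gaussian mixture fitted to its log10 counts; 2499 barcodes (17.3%) carried 2 or more hashtags and 715 none, and both were left out. Scrublet, with an expected rate of 0.1, marked 1971 barcodes (13.6%), of which 826 carried 1 hashtag and were also removed. The remaining 10434 cells had a median of 3275.5 UMIs and 1386 genes. Doublets of cells from the same mouse that Scrublet missed remain.

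Counts were scaled to 10000 per cell and log-transformed, and 2000 variable genes, without T cell receptor genes and without the 163 genes of the fixed outcome lists, gave 30 principal components, 15 neighbours and Leiden clusters at resolution 0.8 (scanpy 1.11.5, igraph 0.11.9, Python 3.11.15). Classes were named from markers fixed before the data were examined, with at least 3 detected markers. CD8 T cells had a Cd8a or Cd8b1 UMI and no Cd4 UMI, so Cd4 is 0 in them by definition, and were clustered again into states. The clusters that scored highest for progenitor exhausted and for exhausted markers were joined as Pdcd1-high after their values were seen: Pdcd1 was at 655 and 760 CPM (counts scaled to 1e6) and the progenitor marker Tcf7 at 60.9 and 28.7 CPM. They differed in Xcl1 (1647 and 69.1 CPM), Csf2 (32.4 and 3.41) and Ifng (679 and 289). The cluster that scored highest for short-lived effector markers was named Ly6c2-Cxcr3 after its values were seen; Cxcr3 had been left out of clustering. A low-UMI cluster of 875 cells (median 985 UMIs) and 1449 T cells of undetermined lineage stayed unnamed and entered no contrast.

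UMI counts were summed per mouse and class and tested with edgeR's quasi-likelihood test (edgeR 4.0.16, limma 3.58.1, R 4.3.3), with TMM factors and edgeR's expression filter. LR was compared with PBS, 4 mice against 4, in CD8 T cells and in each class with at least 20 cells in every mouse. Each T cell class of at least 200 cells was also compared with all other T cells of the same mice, with mouse as a block. Classes were drawn from the same expression values, so the p-values between classes describe them and do not test whether they exist. Benjamini-Hochberg adjusted p-values of 0.05 or less were called. The 13 gene lists, fixed before the data were examined, were tested with camera at its preset correlation, with camera at an estimated correlation, and with fry, where at least 3 members were measured. Shares of cells and numbers of T cell receptor segments were compared with two-sided exact permutation tests, whose smallest p is 0.0286 for 4 mice against 4 and 0.0078 for sign flips over 8 mice. The plan gave no test for class shares in 1 library; the exact test was added once the hashtags were seen to name the mice. Odds ratios for co-detection were Mantel-Haenszel estimates over class and 10 depth bins, with 95% intervals for counting error only, set beside 200 genes of matched detection. Intervals of single shares are exact Clopper-Pearson intervals.

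Named genes followed a rule fixed before the data were examined. Ahr, Ifng, Crem, Prdm1, Cd8a, Cd8b1 and Cd4 were always included. Each class contrast added up to 3 members per list with the largest log2 ratio, and the 5 highest and 5 lowest genes outside clustering genes and markers, all with a UMI in at least 5% of cells, past the adjusted threshold and in the same direction in all 8 mice. Genes named outside this rule were chosen after their values were seen, and the text says so. Locations are those of GENCODE M21 on GRCm38.

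In simulated counts with the same means and library sizes and 200 altered genes, the treatment test recovered 66% of 2-fold changes in CD8 T cells (9831 genes), 84% in naive-like cells (6593 genes) and 72% in regulatory T-like cells (4923 genes). The class test recovered 76% of 2-fold changes in the Pdcd1-high contrast (9922 genes) and 64% in the regulatory T-like contrast (9880 genes). No gene was called in the wrong direction in those simulations. Unaltered genes made up 10 of 137 calls in CD8 T cells, 8 of 160 in naive-like and 5 of 149 in regulatory T-like cells in the treatment test. They made up 8 of 161 calls in the Pdcd1-high and 13 of 148 in the regulatory T-like contrast of the class test. Of 1.5-fold changes, the treatment test recovered 10% in CD8 T cells and 24% in CD8 T cells without naive-like ones.

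Alternatives covered DESeq2 1.42.0, no expression filter, leaving out each mouse, other scalings, equal weight per cell, thinning cells to 1500 UMIs, other cluster resolutions (0.5 and 1.2), other cell filters, no doublet removal and no mouse block. Cells with under 1500 UMIs were dropped before thinning, and clusters and classes were then drawn again. Added after seeing the data were a hashtag call at 80% of hashtag UMIs, contrasts within CD8 T cells only, keeping the low-UMI cluster, leaving out mice for the shares, treatment contrasts under other cell filters, doublet settings and resolutions, and CD8 T cells without the naive-like ones.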

Results

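T cells from melanoma tumours of C57BL/6J mice were profiled as single cells, with 4 mice that received the bacterium Lactobacillus reuteri (LR) and 4 that received PBS. The series title links a tryptophan catabolite of this bacterium to immune checkpoint therapy. The comparisons therefore asked which T cell states the tumours held, how these states differed in expression, including of the aryl hydrocarbon receptor gene Ahr, and how LR differed from PBS mice. After filtering, 10434 cells were assigned to mice: 1305, 1018, 483 and 987 to LR mice 1 to 4, and 618, 2603, 1643 and 1777 to PBS mice 6 to 9. Their gene UMIs totalled 2640252 to 9346186 per mouse, and the median per cell was 2954 to 3615.

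CD8 T cells made up 5200 of the 10434 cells. They fell into naive or central memory-like cells (2783), Pdcd1-high clusters (1134), a Ly6c2-Cxcr3 cluster (867), cycling cells (362) and interferon-responsive-like cells (54). Although the labels describe a CD8+ sort, 1971 CD4 T-like and 638 regulatory T-like cells were also present, with 143 NK-like and 158 myeloid-like cells. Cycling cells were the deepest CD8 state, with a median of 12168 UMIs against 3618 in naive-like cells.

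CD8 T cells were 56.9% ± 11.2 of cells in LR mice and 47.0% ± 15.2 in PBS mice (SD, n = 4 each; exact permutation p = 0.343). CD4 T-like cells were 9.15% ± 3.14 against 21.1% ± 12.5 (exact permutation p = 0.143), and regulatory T-like cells 9.33% ± 5.22 against 5.73% ± 3.14 (exact permutation p = 0.257). Among CD8 T cells, Pdcd1-high cells were 34.6% ± 16.3 in LR and 18.3% ± 13.6 in PBS mice (exact permutation p = 0.229), and cycling cells 12.1% ± 6.54 against 6.47% ± 4.95 (exact permutation p = 0.286). Naive-like cells were 34.4% ± 17.6 against 55.8% ± 27.4 (exact permutation p = 0.343), with 90.2% in PBS mouse 7. The Ly6c2-Cxcr3 cluster was 17.1% ± 7.50 against 18.6% ± 10.4 (exact permutation p = 0.8286). None of these 7 differences passed, the smallest Benjamini-Hochberg value of the exact permutation tests being 0.400. The sort for CD8 can itself set the share of CD4-expressing cells.

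**Figure D1:**
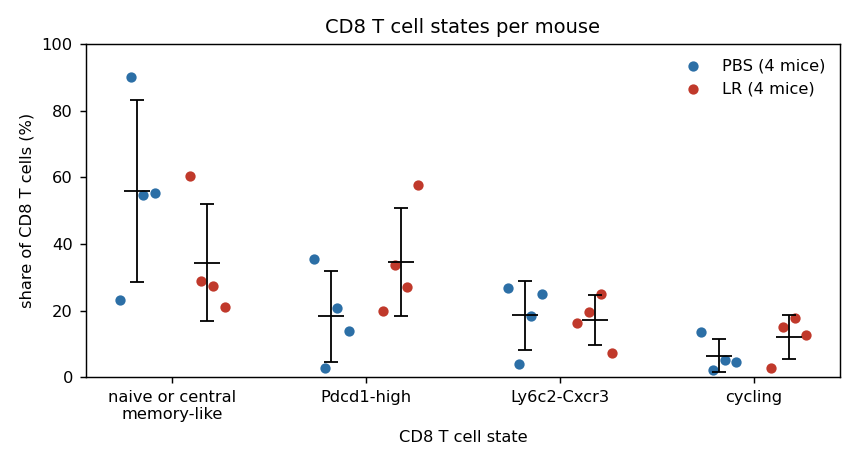
Share of CD8 T cells (%, vertical axis) in each of 4 states (horizontal axis); each point is 1 mouse, and black marks show mean ± SD of 4 mice per treatment. LR and PBS mice overlap in every state, and the mean of the Pdcd1-high state is 34.6% in LR and 18.3% in PBS mice.

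In CD8 T cells as a whole, Gzmb, which encodes the cytotoxic protease granzyme B, averaged 708 ± 184 CPM (counts scaled to 1e6) in LR mice and 317 ± 156 in PBS mice (SD, n = 4 each), a log2 ratio of 1.16 ± 0.35 (SE; edgeR adjusted p = 0.680). Ifng, which encodes interferon gamma, averaged 233 ± 71.0 against 138 ± 71.5 CPM. Crem, a regulator of cyclic AMP responses, averaged 38.5 ± 11.5 against 24.0 ± 6.31 CPM, and Prdm1, which encodes the transcription factor Blimp-1, 40.3 ± 18.6 against 22.4 ± 11.01 CPM. Ahr was at 13.8 ± 4.52 against 16.1 ± 4.91 CPM. None of these differences passed correction. edgeR called 0 of 9831 genes, with 626 at an unadjusted p under 0.05, and DESeq2 called 3 (Plac8, Smyd1 and Adrb1), named after their values were seen.

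Once naive-like cells were set aside, a comparison added after seeing the data, Gzmb was the only gene of 9128 that edgeR called. It was at 929 ± 85.9 CPM in LR and 563 ± 39.3 in PBS mice, with all 4 LR mice above all 4 PBS mice (log2 ratio 0.72 ± 0.09; adjusted p = 0.0268). Gzmb (ENSMUSG00000015437) lies on chromosome 14 at 56258838 to 56262260 and codes for protein. It was singled out after its values were seen. DESeq2 called Gzmb and Plac8, and 379 genes had an unadjusted p under 0.05 in edgeR. With 1 mouse left out, the adjusted p for Gzmb ranged from 0.0104 to 0.296 and passed only without LR mouse 1, while the log2 ratio stayed between 0.68 and 0.79.

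Within single CD8 states, Gzmb was at 1140.5 ± 304 against 685 ± 87.8 CPM in Pdcd1-high cells and at 1022 ± 395 against 672 ± 79.8 CPM in cycling cells, neither passing correction (adjusted p = 0.977 and 0.985). In the Ly6c2-Cxcr3 cluster Gzmb was at 360 ± 173 against 294 ± 61.7 CPM (edgeR adjusted p = 0.999). There LR mouse 1 reached 607 CPM and the other LR mice 230 to 346. In naive-like cells Gzmb was at 40.2 ± 27.6 against 24.6 ± 5.91 CPM (edgeR adjusted p = 0.958). edgeR called 0 of 7237 genes in Pdcd1-high cells (290 at an unadjusted p under 0.05; DESeq2 called Plac8). It called 0 of 6463 in cycling cells (289; DESeq2 called Lars2), 0 of 4727 in the Ly6c2-Cxcr3 cluster (195; DESeq2 0) and 0 of 3813 in CD4 T-like cells (179; DESeq2 called Dnajb1). Ifng in Pdcd1-high cells averaged 512 ± 369 CPM in LR mice, where LR mouse 1 alone reached 1066, and 354 ± 96.6 in PBS mice. The 2 clusters joined in this class had Ifng at 679 and 289 CPM, so their mix in each mouse, which was not tested, can shift these values. In every class, 2.62% to 3.86% of genes had LR and PBS mice without overlap, against the 2.86% that chance gives.

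In naive-like CD8 T cells the T cell receptor beta variable segment Trbv12-2 was lower in LR mice, at 31.0 ± 17.1 CPM against 119 ± 19.9, with all 4 LR mice below all 4 PBS mice. Its log2 ratio was −1.69 ± 0.21 (SE; adjusted p = 0.000397), the only call among 6593 genes in edgeR, with 321 at an unadjusted p under 0.05. DESeq2 also called Ly6a. Trbv12-2 (ENSMUSG00000094525) lies on chromosome 6 at 41118851 to 41119364 and is a receptor variable gene, close to Trbv12-1 at 41113550 to 41114067. These segments were 88.3% identical over 385 aligned bases, so counts between them carry that uncertainty. Cells whose leading segment was Trbv12-2 were 3.18% ± 1.26 in LR mice (31 of 840) and 7.19% ± 1.38 in PBS mice (132 of 1793; exact permutation p = 0.0286, the smallest this design allows; Benjamini-Hochberg 0.543 over 19 segments).

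In regulatory T-like cells, Jun, which encodes a subunit of the AP-1 transcription factor, was lower in LR mice, at 163 ± 24.0 CPM against 333 ± 18.4. The log2 ratio was −0.98 ± 0.14 (SE; adjusted p = 0.00354), with all 4 LR mice below all 4 PBS mice. Jun (ENSMUSG00000052684; chromosome 4, 95049034 to 95052222, protein-coding) was the only call among 4923 genes in edgeR, with 307 at an unadjusted p under 0.05, and DESeq2 also called Ctla2a and Cd69. Both Trbv12-2 and Jun were named because each was the single call. LR mouse 1 contributed 21 regulatory T-like cells.

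**Figure D2:**
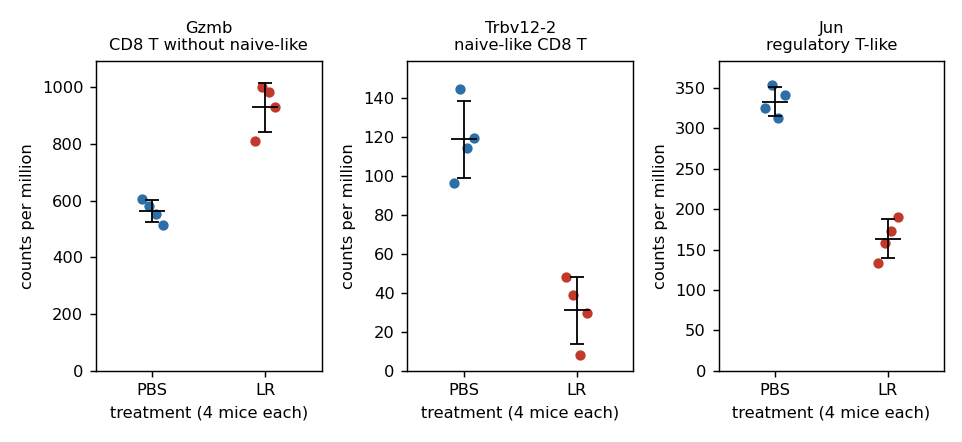
CPM (vertical axes, each from 0) of Gzmb in CD8 T cells without naive-like ones, Trbv12-2 in naive-like CD8 T cells and Jun in regulatory T-like cells; each point is 1 of 4 mice per treatment, with mean ± SD in black. LR mice average 929, 31.0 and 163 against 563, 119 and 333 in PBS mice, with no overlap in any panel.

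Among the fixed lists, cytotoxic molecules in CD8 T cells had a median log2 ratio of 0.68 in LR over PBS mice (camera adjusted p = 4.63e-06, adjusted p = 0.327 with an estimated correlation), with 0 of 12 members higher over all genes and 2 adjusted over the list alone. Glycolysis (median 0.38; camera adjusted p = 8.12e-08), effector transcription factors (0.33; adjusted p = 0.000373) and costimulatory receptors (0.32; adjusted p = 0.0143) were lost with an estimated correlation (adjusted p = 0.457 for each), with no member past the threshold either way. In the same cells, markers of exhausted CD8 T cells had a median of 0.61 (adjusted p = 3.97e-06, adjusted p = 0.462 with an estimated correlation) and markers of naive cells −0.75 (adjusted p = 0.000186, adjusted p = 0.462 with an estimated correlation). Cycling markers had a median of 0.45 (camera adjusted p = 0.0115, adjusted p = 0.577 with an estimated correlation). The 2 tested B cell markers had a median of −1.02 (camera adjusted p = 0.0206, adjusted p = 0.462 with an estimated correlation). All 6 in the matrix summed to 67.9 ± 31.9 against 117 ± 57.0 CPM.

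Without naive-like cells the cytotoxic list kept its call with an estimated correlation (median 0.33; camera adjusted p = 1.49e-05, adjusted p = 0.0311 with an estimated correlation, fry adjusted p = 0.163). Gzmb was its only member past the threshold, over all genes and adjusted over the list alone. Exhausted markers in these cells had a median of 0.32 (camera adjusted p = 5.22e-05, adjusted p = 0.743 with an estimated correlation), and naive or central memory markers −0.39 (camera adjusted p = 0.00691, adjusted p = 0.743 with an estimated correlation). Differences of mix are not excluded there. In regulatory T-like cells, chemokine receptors and homing genes had a median of −0.38 (camera adjusted p = 6.05e-05, adjusted p = 0.0456 with an estimated correlation, fry adjusted p = 0.0299), with 0 of 8 lower over all genes and 1 adjusted over the list alone. Markers of naive or central memory cells moved alike there (median −0.39, camera adjusted p = 0.0191, adjusted p = 0.219 with an estimated correlation), as did 2 CD4 T markers (−0.30, camera adjusted p = 0.0191, adjusted p = 0.199 with an estimated correlation), and 5 short-lived effector markers (−0.44, camera adjusted p = 2.64e-05, adjusted p = 0.199 with an estimated correlation, 3 lower over the list alone), so a shift of cell content is not set apart from the homing call. Heat shock and dissociation genes had a median of −0.14 there (camera adjusted p = 4.11e-06, adjusted p = 0.0691 with an estimated correlation); Jun alone was lower over all genes and 3 members adjusted over the list alone. The AhR complex list did not pass in any class, with a median of −0.11 in CD8 T cells (camera adjusted p = 0.559). Nor did tryptophan handling (0.09, camera adjusted p = 0.566) or the CREB and cyclic AMP response (median −0.05 but mean 0.04, camera adjusted p = 0.877) in CD8 T cells.

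The list calls in this paragraph were all lost with an estimated correlation. In naive-like cells, interferon gamma response genes had a median of 0.24 (camera adjusted p = 0.000539, adjusted p = 0.517 with an estimated correlation), with 0 of 12 higher over all genes and 4 adjusted over the list alone. Effector transcription factors (0.28, camera adjusted p = 0.0214, adjusted p = 0.517 with an estimated correlation) had 1 higher over the list alone, and glycolysis (0.15, camera adjusted p = 0.00280, adjusted p = 0.554 with an estimated correlation) none. In the same cells CD8 T markers had a median of −0.18 (camera adjusted p = 0.00546, adjusted p = 0.409 with an estimated correlation, 2 lower over the list alone) and 2 B cell markers −0.53 (camera adjusted p = 0.0273, adjusted p = 0.409 with an estimated correlation, both lower over the list alone). Cytotoxic molecules had a median of 0.20 in Pdcd1-high cells (camera adjusted p = 0.0146, adjusted p = 0.215 with an estimated correlation, 1 higher over the list alone) and 0.43 in cycling cells (camera adjusted p = 0.00292, adjusted p = 0.516 with an estimated correlation). Oxidative phosphorylation was at −0.11 in cycling cells (camera adjusted p = 0.0357, adjusted p = 0.646 with an estimated correlation) and 0.14 in regulatory T-like cells (camera adjusted p = 0.00575, adjusted p = 0.225 with an estimated correlation). In CD4 T-like cells, interferon gamma response genes were at 0.35 (camera adjusted p = 0.0175, adjusted p = 0.375 with an estimated correlation), glycolysis at 0.32 (camera adjusted p = 0.00148, adjusted p = 0.631 with an estimated correlation) and heat shock and dissociation genes at 0.20 (camera adjusted p = 0.00148, adjusted p = 0.375 with an estimated correlation, 1 higher over the list alone). Their interferon-responsive markers were at 0.53 (2 members, camera adjusted p = 0.0236, adjusted p = 0.241 with an estimated correlation) and CD8 T markers at −0.20 (camera adjusted p = 0.0390, adjusted p = 0.257 with an estimated correlation). Glycolysis was at 0.17 in Pdcd1-high cells (camera adjusted p = 0.0146, adjusted p = 0.739 with an estimated correlation), 0.21 in regulatory T-like cells (camera adjusted p = 0.00575, adjusted p = 0.361 with an estimated correlation) and 0.17 in CD8 T cells without naive-like ones (camera adjusted p = 0.000954, adjusted p = 0.798 with an estimated correlation). In regulatory T-like cells, cycling markers (0.48, camera adjusted p = 0.0191, adjusted p = 0.325 with an estimated correlation) and interferon-responsive markers (0.46, camera adjusted p = 0.0191, adjusted p = 0.324 with an estimated correlation) moved up too.

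Naive or central memory-like CD8 T cells held little effector message when set against all other T cells of the same 8 mice. Ifng was at 13.1 ± 4.20 CPM against 189 ± 136 (SD, n = 8), a log2 ratio of −3.74 ± 0.29 (SE; adjusted p = 1.32e-08; lower in 8 of 8 mice). The chemokine genes Ccl3 (−4.60 ± 0.24) and Ccl4 (−3.77 ± 0.19) were lower, as were the granzyme genes Gzmk (−4.49 ± 0.26) and Gzmb (−4.02 ± 0.17), all in 8 of 8 mice. Of 14 measured cytokine genes 13 were lower, over all genes and adjusted over the list alone (camera adjusted p = 2.59e-16, adjusted p = 0.00616 with an estimated correlation). Cytotoxic molecules were lower in 13 of 14 by both counts (adjusted p = 0.00228 with an estimated correlation), and effector transcription factors in 10 of 12 by both counts (adjusted p = 0.0214 with an estimated correlation), with Irf8 at −3.49 ± 0.24 and Bhlhe40 at −3.10 ± 0.14. Costimulatory receptors were lower in 7 of 9 by both counts (adjusted p = 0.00124 with an estimated correlation), led by Tnfrsf4 (−3.76 ± 0.14). Glycolysis was lower in 12 of 13, or 13 adjusted over the list alone (adjusted p = 0.0292 with an estimated correlation), led by Tpi1 (−1.83 ± 0.12). Prdm1 (−2.87 ± 0.22) and Crem (−1.12 ± 0.17) were lower too.

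Among genes outside clustering genes and markers that met the naming rule, Ccr9, a gut-homing chemokine receptor, had the highest log2 ratio in these cells. It was at 70.3 ± 23.2 against 1.71 ± 0.898 CPM (log2 ratio 5.30 ± 0.17, edgeR adjusted p = 2.64e-13, 8 of 8 mice), followed by Trnp1 (4.90 ± 0.21), Tmem108 (3.72 ± 0.24), Cxxc5 (3.32 ± 0.22) and Plekho1 (3.31 ± 0.16). Ahr was also higher, at 21.8 ± 5.98 against 11.3 ± 2.58 CPM (0.91 ± 0.16; adjusted p = 0.000122, 8 of 8 mice), with Pde4b (1.28 ± 0.15) and the interferon-response gene Irf1 (0.98 ± 0.15). The Ahr values are shares of all UMIs. An Ahr UMI was found in 6.40% of naive-like cells (median 3618 UMIs per cell), 7.94% of Pdcd1-high cells (median 5587.5) and 7.73% of cycling cells (median 12168). Heat shock and dissociation genes were higher in 9 of 12, or 10 adjusted over the list alone (camera adjusted p = 0.00658, adjusted p = 0.234 with an estimated correlation). Oxidative phosphorylation genes were lower in 9 of 14 by both counts (camera adjusted p = 0.0254, adjusted p = 0.587 with an estimated correlation). edgeR called 2147 genes higher and 2268 lower of 10210. Scaling by library totals gave 1025 and 3971 and moved the median of all genes by −0.24, and equal weight per cell gave 572 and 3546 with a median of −0.31.

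Pdcd1-high CD8 T cells had the chemokine gene Ccl3 at 969 ± 320 CPM against 125 ± 87.2 in all other T cells (log2 ratio 3.19 ± 0.33; adjusted p = 3.31e-06, 8 of 8 mice). Ccl1 (3.45 ± 0.37) and Ccl4 (2.97 ± 0.31) were higher too. Ifng was at 418 ± 255 against 69.6 ± 36.8 CPM (adjusted p = 1.21e-05, 8 of 8 mice) and the perforin gene Prf1 at 371 ± 171 against 83.4 ± 41.4 CPM (2.16 ± 0.14). The transcription factor genes Irf8 (2.18 ± 0.26) and Zeb2 (1.81 ± 0.19), the orphan receptor gene Nr4a2 (2.20 ± 0.21), the tissue-homing receptor gene Cxcr6 (2.19 ± 0.14) and Adgrg1 (4.08 ± 0.24) were higher. Jun (−1.82 ± 0.14), Fos (−1.88 ± 0.15), Irf1 (−1.43 ± 0.10), Itgae (−4.70 ± 0.32) and Ccr9 (−5.16 ± 0.40) were lower. Ahr did not pass (14.2 ± 4.20 against 14.6 ± 4.82 CPM; adjusted p = 0.856).

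Cytokines were higher in 9 of 13 members of that list and lower in 2, by both counts. Cytotoxic molecules were higher in 10 of 14, or 11 adjusted over the list alone, and effector transcription factors in 11 of 12, or 12 adjusted over the list alone. Their camera calls (adjusted p = 2.54e-07, 1.37e-09 and 7.46e-10) were lost with an estimated correlation (adjusted p = 0.104 for each). Heat shock and dissociation genes were lower in 7 of 12 by both counts (camera adjusted p = 0.00199, adjusted p = 0.104 with an estimated correlation). Glycolysis was higher in 9 of 13 by both counts (camera adjusted p = 0.00582) and oxidative phosphorylation in 7 of 14, or 9 adjusted over the list alone (camera adjusted p = 0.0176), both lost with an estimated correlation (adjusted p = 0.504 for each). edgeR called 1633 genes higher and 1826 lower of 9922.

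The Ly6c2-Cxcr3 cluster had the chemokine receptor gene Cxcr3, used in its name, at 388 ± 85.3 CPM against 94.2 ± 40.9 (log2 ratio 2.12 ± 0.12; adjusted p = 4.05e-12, 8 of 8 mice). Ccl5 was at 7964 ± 1911 against 3043 ± 1381 CPM (1.55 ± 0.21), and Ccr2 (1.13 ± 0.15), Samd3 (2.23 ± 0.20), Ifitm10 (1.57 ± 0.13) and Tbx21, which encodes T-bet (1.27 ± 0.16), were higher. The costimulatory receptor genes Tnfrsf4 (−3.43 ± 0.16) and Tnfrsf9 (−3.07 ± 0.22), and Ccl3 (−3.14 ± 0.22), Csf1 (−2.82 ± 0.28), Irf8 (−2.45 ± 0.19) and Prdm1 (−2.02 ± 0.25) were lower, each in 8 of 8 mice. Chemokine receptors and homing genes were higher in 7 of 12 and lower in 2 by both counts, and their call held with an estimated correlation (camera adjusted p = 1.69e-06, adjusted p = 0.0119 with an estimated correlation). Cytokines were lower in 8 of 14 (adjusted p = 0.156 with an estimated correlation) and glycolysis in 8 of 12 (adjusted p = 0.188 with an estimated correlation), both by both counts. Ifng (128 ± 37.2 against 159 ± 93.2 CPM; adjusted p = 0.562) and Ahr (14.7 ± 7.34 against 14.6 ± 3.55 CPM) did not pass. Camera calls lost with an estimated correlation were costimulatory receptors, lower in 3 of 9 by both counts (adjusted p = 0.188 with an estimated correlation), and oxidative phosphorylation, lower in 4 of 14, or 9 adjusted over the list alone (adjusted p = 0.423 with an estimated correlation). Heat shock and dissociation genes were lower in 6 of 12, or 7 adjusted over the list alone (adjusted p = 0.226 with an estimated correlation). edgeR called 710 genes higher and 1117 lower of 9740. Library totals gave 867 and 909, and equal weight per cell 504 and 504.

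Cycling CD8 T cells had Plk1, which encodes a mitotic kinase and was not used for clustering, at 93.4 ± 12.6 against 2.09 ± 0.794 CPM (log2 ratio 5.38 ± 0.17; adjusted p = 1.86e-13, 8 of 8 mice), Mxd3 (6.08 ± 0.27), Esco2 (5.78 ± 0.28), Pimreg (5.29 ± 0.25) and Ska1 (5.25 ± 0.21). The class was named from markers of cycling cells, so a higher mitotic gene follows from how it was drawn and is no independent test. Oxidative phosphorylation genes were higher in 13 of 14 by both counts, led by Cox5a (0.87 ± 0.09) (camera adjusted p = 0.000178, adjusted p = 0.486 with an estimated correlation). Glycolysis was higher in 9 of 12 and lower in 1 by both counts, led by Tpi1 (1.21 ± 0.17) (camera adjusted p = 0.0252, adjusted p = 0.486 with an estimated correlation). The amino acid transporter gene Slc7a5, which carries tryptophan among other substrates, was at 73.4 ± 12.4 against 33.3 ± 3.75 CPM (1.14 ± 0.11). Hsp90aa1 (1.01 ± 0.08) and Gzmk (1.21 ± 0.21) were higher. Jun (−2.01 ± 0.18), Fos (−1.84 ± 0.11), Irf1 (−1.60 ± 0.09), Cd69 (−1.50 ± 0.10) and Icos (−1.44 ± 0.14) were lower. Interferon gamma response genes were lower in 8 of 12, or 9 adjusted over the list alone (camera adjusted p = 0.0112, adjusted p = 0.486 with an estimated correlation). Ahr was at 6.27 ± 2.9996 against 15.9 ± 4.15 CPM (−1.31 ± 0.30; adjusted p = 0.00132, 7 of 8 mice). These Ahr values are shares of all UMIs. An Ahr UMI was found in 7.73% of cycling cells (median 12168 UMIs per cell) and in 6.40% of naive-like cells (median 3618). At such unlike depth these shares cannot be compared, so they do not tell whether fewer cycling cells would show an Ahr UMI at equal depth. The CREB and cyclic AMP response was lower in 11 of 16 by both counts (camera adjusted p = 0.00453, adjusted p = 0.311 with an estimated correlation). Homing genes were lower in 6 of 11 (camera adjusted p = 0.0349) and heat shock and dissociation genes in 7 of 12 (camera adjusted p = 0.0252), by both counts, and neither call held (adjusted p = 0.486 with an estimated correlation for each). edgeR called 2417 genes higher and 2562 lower of 9271.

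CD4 T-like cells had Cd40lg, which encodes the ligand of CD40, at 65.6 ± 15.9 against 3.29 ± 1.28 CPM (log2 ratio 4.39 ± 0.20; adjusted p = 8.84e-16, 8 of 8 mice). Pdlim4 (6.16 ± 0.23), Acvrl1 (3.21 ± 0.35) and Trat1 (2.45 ± 0.18) were higher. The immediate early genes Jun, at 1011 ± 177 against 262 ± 98.7 CPM (1.99 ± 0.16), Junb (1.71 ± 0.10) and Fos (1.67 ± 0.15) were higher, within a heat shock and dissociation list higher in 8 of 12, or 9 adjusted over the list alone (camera adjusted p = 6.71e-05, adjusted p = 0.121 with an estimated correlation). Cytotoxic molecules were lower in 13 of 14 by both counts (adjusted p = 0.0163 with an estimated correlation), with Nkg7 at −4.25 ± 0.12 and Gzmb at −4.30 ± 0.17. Cytokines were lower in 12 of 13 by both counts (adjusted p = 0.0402 with an estimated correlation). Ahr was at 5.56 ± 3.64 against 15.5 ± 4.52 CPM (−1.29 ± 0.27; adjusted p = 0.000374, 8 of 8 mice). Effector transcription factors were lower in 9 of 12 by both counts (adjusted p = 0.0163 with an estimated correlation), with Tbx21 at −3.23 ± 0.24. Costimulatory receptors (7 of 9), homing genes (9 of 11) and oxidative phosphorylation (12 of 14) were lower by both counts but lost their calls (adjusted p = 0.121 with an estimated correlation for each), as did glycolysis, lower in 13 of 13 (adjusted p = 0.151 with an estimated correlation). edgeR called 1892 genes higher and 2421 lower of 10463. Equal weight per cell gave 826 and 2139, with the median of all genes moved by −0.24.

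Regulatory T-like cells had Areg, which encodes amphiregulin, at 154 ± 102 against 4.41 ± 3.01 CPM (log2 ratio 5.15 ± 0.20; adjusted p = 2.28e-12, 8 of 8 mice). Il10 (5.10 ± 0.20) and Ebi3, a subunit of interleukin 35 (4.49 ± 0.18), were higher. The receptor genes Tnfrsf4, at 1364 ± 263 against 126 ± 75.4 CPM (3.59 ± 0.22), Icos (2.79 ± 0.13), Tnfrsf18 (2.34 ± 0.15) and Ccr2 (2.81 ± 0.27) were higher, as were Prdm1 (2.15 ± 0.23), Crem (2.04 ± 0.15) and Gbp7 (1.38 ± 0.10). Eomes (−4.20 ± 0.34), Gzmk (−3.96 ± 0.45), Pde3b (−3.51 ± 0.24), Fasl (−3.11 ± 0.25) and Slc7a5 (−1.13 ± 0.23) were lower. Costimulatory receptors were higher in 7 of 9 and lower in 2 by both counts (camera adjusted p = 1.36e-08, adjusted p = 0.0501 with an estimated correlation). Glycolysis was higher in 12 of 12 by both counts (camera adjusted p = 4.05e-07, adjusted p = 0.292 with an estimated correlation). Cytokines were higher in 3 of 13 and lower in 6 by both counts, with a median of −1.10 while the test pointed up (camera adjusted p = 0.764). Interferon gamma response genes were higher in 7 of 12 by both counts (camera adjusted p = 0.00159, adjusted p = 0.389 with an estimated correlation). Cytotoxic molecules were lower in 12 of 14 by both counts (camera adjusted p = 1.54e-05, adjusted p = 0.274 with an estimated correlation), and heat shock and dissociation genes in 9 of 12, or 10 adjusted over the list alone (camera adjusted p = 0.00145, adjusted p = 0.274 with an estimated correlation). The AhR target list was measured in this class alone, with 2 of 3 members higher by both counts (camera adjusted p = 0.381). Ahr itself did not pass (18.5 ± 8.30 against 14.3 ± 3.96 CPM; adjusted p = 0.132). edgeR called 1704 genes higher and 1795 lower of 9880. Library totals gave 2301 and 1295, moving the median by 0.10, and equal weight per cell 1716 and 1090.

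**Figure D3:**
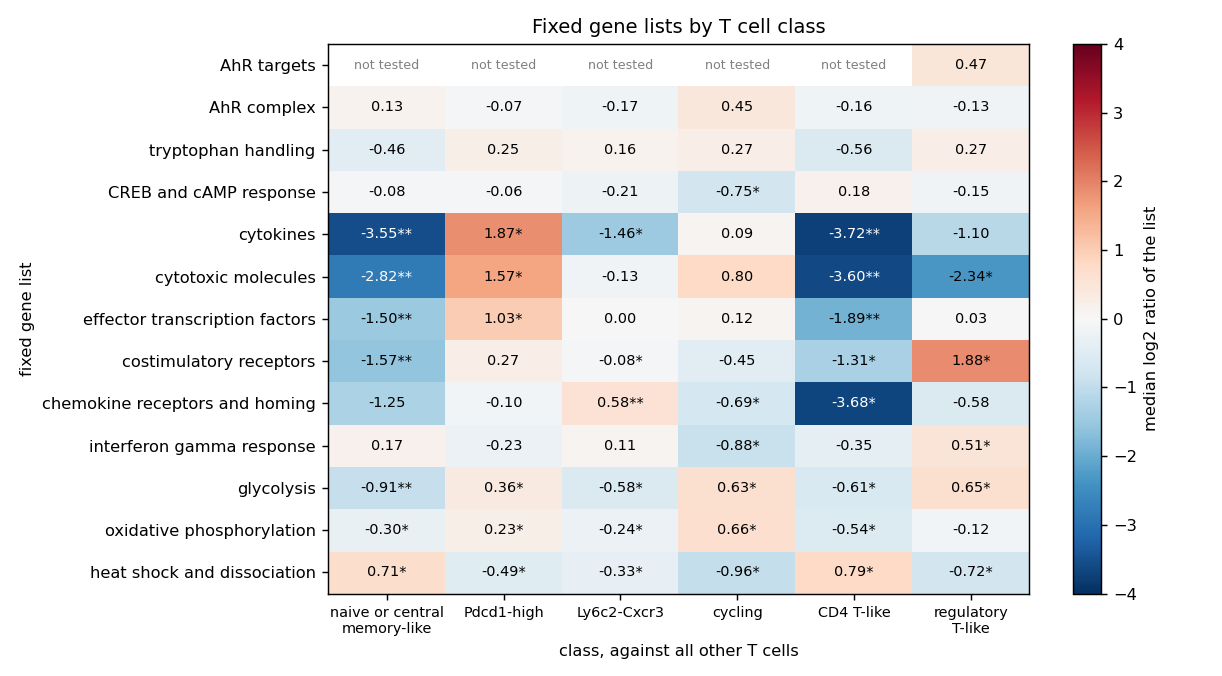
Median log2 ratio of each fixed gene list (vertical axis) in each T cell class against all other T cells of the same 8 mice (horizontal axis), by colour and number. One star marks a camera adjusted p under 0.05 and a double star one that also holds with an estimated correlation, as for cytokines in naive-like cells (−3.55) and homing genes in the Ly6c2-Cxcr3 cluster (0.58).

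An Ifng UMI was found in 24.3% of CD8 T cells (95% interval 23.1 to 25.5; median 3885 UMIs per cell), in 61.5% of Pdcd1-high and 62.4% of cycling cells, and in 2.73% of naive-like cells. The like shares of Pdcd1-high and cycling cells came at unlike depth. Pooled over cells, Ifng was at 456 CPM in Pdcd1-high cells (median 5587.5 UMIs per cell) and at 163 CPM in cycling cells (median 12168). CD4 T-like cells gave 1.67% (median 2880 UMIs per cell) and myeloid-like cells 10.1% (median 1436.5), so neither gives a clean level for free RNA. An Ahr UMI was found in 6.67% of CD8 T cells (95% interval 6.01 to 7.39), in 1.93% of CD4 T-like cells and in 15.4% of NK-like cells. Among 7809 T cells, 26.0% of the 438 with an Ahr UMI also had an Ifng UMI, against 16.8% of the others. Within class and depth the odds ratio was 1.28 (95% interval 0.945 to 1.73; above 1 in 7 of 8 mice), at the 94.5th percentile of 200 genes of matched detection. Tbx21 gave 1.41 (1.18 to 1.68, 8 of 8 mice), at the 98.5th percentile, while Crem gave 1.01 (0.822 to 1.247) and Prdm1 1.06 (0.851 to 1.31). The interval for Ahr included 1 over these T cells. Within CD8 T cells only, a choice added after seeing the data, the odds ratio was 1.41 and its interval excluded 1, so the call depends on the cells compared.

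T cell receptor usage was narrow in the activated CD8 states. Counted by the leading Trbv segment of each cell, the effective number of segments (the inverse Simpson index) was 4.26 ± 2.31 in Pdcd1-high cells and 16.6 ± 1.28 in naive-like cells (SD, n = 8), lower in 8 of 8 mice (exact sign-flip permutation p = 0.0078, the smallest this design allows; Benjamini-Hochberg 0.0117 over 3 tests). Cycling cells held 5.25 ± 2.10 effective segments (exact permutation p = 0.0078; Benjamini-Hochberg 0.0117, 8 of 8 mice), and the Ly6c2-Cxcr3 cluster 13.6 ± 2.24 (exact permutation p = 0.0156, 7 of 8 mice). Cell numbers were not equalised, and few cells lower this index. Naive-like cells with a segment numbered 65 to 871 per mouse, Ly6c2-Cxcr3 cells 30 to 267 and cycling cells 21 to 73. The small difference of the Ly6c2-Cxcr3 cluster can therefore come from cell number. In LR mice 2 and 4 and PBS mouse 6, Pdcd1-high cells outnumbered naive-like ones and still held fewer effective segments. In Pdcd1-high cells Trbv2 led in 55.8% of cells of LR mouse 1, Trbv16 in 52.4% of LR mouse 3 and 72.1% of PBS mouse 9, Trbv13-2 in 30.8% of PBS mouse 8, and Trbv19 in 56.3% of LR mouse 2, 31.4% of LR mouse 4, 54.4% of PBS mouse 6 and 28.6% of the 28 cells of PBS mouse 7. Pdcd1-high cells of LR and PBS mice held 3.66 ± 1.28 and 4.86 ± 3.14 effective segments (SD, n = 4 each; exact permutation p = 0.600), and naive-like cells 15.8 ± 1.17 and 17.3 ± 0.902 (exact permutation p = 0.0857).

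**Figure D4:**
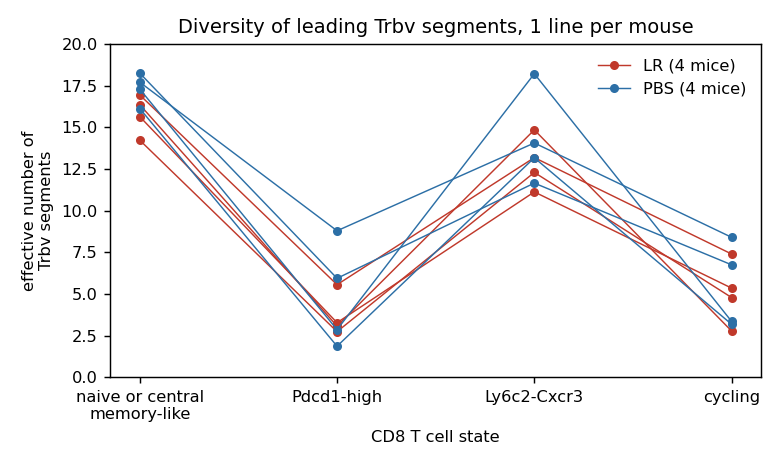
Effective number of leading Trbv segments (vertical axis) in 4 CD8 T cell states (horizontal axis), with 1 line per mouse, coloured by treatment. The Pdcd1-high state averages 4.26 and lies below the naive-like state, which averages 16.6, in all 8 mice.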

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

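The prediction of Gzmb from cell states and the share of cells led by Trbv12-2 were set before their results were seen; the test of Gzmb mouse by mouse, the other explanations weighed here, the tests of differences between classes and the comparison without naive-like cells were chosen only after the results were seen.

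The first pattern is the higher Gzmb of LR mice in CD8 T cells. A different mix of CD8 states, with 1 fixed Gzmb level per state, predicted a log2 ratio of 0.738 where the same statistic observed 1.32 (55.7%), and by the bound set before, 2 SE of the fitted 1.16 ± 0.35, this did not decide. Mouse by mouse, observed over predicted Gzmb was above 1 in 4 of 4 LR mice and below 1 in 4 of 4 PBS mice. The log2 difference was 0.586 ± 0.0865 (SE, exact permutation p = 0.0286, the smallest possible). Gzmb had been singled out for setting the same LR and PBS mice apart without naive-like cells, so this test is not independent of that choice. It cannot decide whether the mix of states is the whole cause. A single mouse as the source is argued against: without any 1 of the 8 mice the ratio in cells other than naive-like ones, less 2 SE, stayed at or above 0.474, though the adjusted p then ranged from 0.0104 to 0.296. Of the 35 splits of the 8 mice, 8 called at least as many genes as the 1 of the real split in these cells (highest other 8), so chance is not excluded, and a finer mix within states and a treatment effect stay open as untested hypotheses.

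The second pattern is the lower Trbv12-2 of LR mice in naive-like CD8 T cells. Reads moved to the similar Trbv12-1 are argued against, since Trbv12-1 differed by −5.41 ± 17.2 CPM where 87.8 more would be needed. By the bound set before, few cells are argued against, since the share of cells led by the segment had an exact permutation p of 0.0286, under 0.05. That share is counted from the same UMIs that singled the segment out. Its Benjamini-Hochberg value over 19 segments, which was not part of that bound, was 0.543. Even the smallest p of this design does not pass over 19 segments unless other segments have small p-values too. That value therefore decides nothing. Few cells are kept open because the share rests on the same UMIs. A difference in the receptor locus is not decided by the CD4 T-like cells, where the log2 ratio was −0.567 ± 0.340. That ratio goes against such a difference by the bound of 2 SE, written after the data were seen. The difference between those classes did not pass its own exact permutation test (p = 0.114). Of the 35 splits, 7 called at least as many genes as the 1 of the real split, the highest other 73, so chance is not excluded, and a treatment effect is no more than a hypothesis.

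The third pattern is the lower Jun of LR mice in regulatory T-like cells. A milder tissue dissociation of the LR tumours that acts alike on all T cells is argued against. The Jun ratio in CD4 T-like and naive-like cells lay at least 1.08 ± 0.19 above that in regulatory T-like cells on the log2 scale. An effect of dissociation, or of handling after the sort, that differs between classes stays open. The heat shock and dissociation list, which holds Jun, was also lower in regulatory T-like cells (median −0.14, camera adjusted p = 4.11e-06, adjusted p = 0.0691 with an estimated correlation). Conventional CD4 T cells among the PBS cells stay open: Foxp3 goes against them by the bound written for it after the data were seen (−0.0412 ± 0.119), but 2 CD4 T markers go with them (median −0.297, camera adjusted p = 0.0191, adjusted p = 0.199 with an estimated correlation), and the naive markers (median −0.392 ± 0.246) lie too close to the −0.491 that was needed. Of the 35 splits, 10 called at least as many genes as the 1 of the real split, the highest other 20, so chance is not excluded. A treatment effect may remain as a hypothesis.

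Differences of the LR effect between classes were tested by exact permutation for these 3 genes, which were chosen because they had been called, so the tests are not independent of the calls. For Trbv12-2 the effect in naive-like cells minus that in Pdcd1-high cells was −2.50, in cycling cells −4.20 and in regulatory T-like cells −3.76 (log2). For Jun the effect in regulatory T-like cells minus that in naive-like cells was −1.11, in Pdcd1-high cells −1.17, in the Ly6c2-Cxcr3 cluster −0.96, in cycling cells −1.07 and in CD4 T-like cells −1.21. Each of these 8 differences had an exact permutation p of 0.0286, the smallest possible, and a Benjamini-Hochberg value of 0.0464 over 13 tests. The Jun tests all reuse the same regulatory T-like values, and the Trbv12-2 tests the same naive-like values. They are therefore not separate results, and the Benjamini-Hochberg value passes only because so many tests share the smallest p. The other 5 did not pass: Trbv12-2 against the Ly6c2-Cxcr3 cluster (−1.51, exact permutation p = 0.457) and CD4 T-like cells (−1.71, exact permutation p = 0.114), and Gzmb in CD8 T cells without naive-like ones against naive-like (0.24, exact permutation p = 0.629), CD4 T-like (0.68, exact permutation p = 0.200) and regulatory T-like cells (0.58, exact permutation p = 0.400).

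Single mice stood apart from the other 3 of their group in 12 of 132 groups tested, where chance alone gives about 1 in 20. LR mouse 1 had the lowest Gzmb in CD8 T cells (432 CPM, the others 793 to 805), the highest Ifng in Pdcd1-high cells (1066, others 325 to 329) and in CD8 T cells without naive-like ones (634, others 209 to 270), and the lowest Ifng in cycling cells (83.1, others 173 to 182). In its 21 regulatory T-like cells Gzmb was 2544 CPM (others 580 to 750) and Cd8b1 293 CPM (others 46.5 to 51.6). LR mouse 2 had the highest Cd8b1 in Pdcd1-high cells (1523 CPM, others 1250 to 1283) and Ifng in the Ly6c2-Cxcr3 cluster (169, others 117 to 123). PBS mouse 7 had the highest Cd8a in naive-like cells (561 CPM, others 428 to 434) and the lowest Ifng in CD8 T cells without naive-like ones (157, others 248 to 261). PBS mouse 8 had the highest Crem there (35.7 CPM, others 32.2 to 32.5), and PBS mouse 9 had 16.4 effective Trbv segments in regulatory T-like cells (others 10.3 to 10.8).

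A ninth hashtag, named for LR mouse 5, held 5699 UMIs in 3601 of the 16969 barcodes, with at most 181 in 1 barcode. It led in 0 barcodes, and no cell was assigned to it.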

How the results depend on the processing

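The contrasts within CD8 T cells only, the 80% hashtag call, keeping the low-UMI cluster, leaving mice out of the shares, the treatment contrasts under other cell filters, doublet settings and resolutions, and CD8 T cells without naive-like ones were chosen only after results were seen; the other alternatives were fixed before the data were examined. All 119 values of the class shares kept their side of the threshold. Of 1752 values for single genes by class, 1685 kept direction and side, 51 lost and 11 gained the threshold and 5 turned; of 836 for single lists, 792, 23, 16 and 5; of 195 for single genes of LR against PBS, 185, 7, 3 and 0. Trbv12-2 in naive-like cells and Jun in regulatory T-like cells passed under all 15 alternatives each, with adjusted p from 3.37e-20 to 0.00810 and from 1.32e-06 to 0.0376.

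Counts of genes for LR against PBS moved with the tool and the filter. DESeq2 called 3 in CD8 T cells, 2 in naive-like, 1 in Pdcd1-high, 1 in cycling, 1 in CD4 T-like and 3 in regulatory T-like cells, and 2 in CD8 T cells without naive-like ones. No expression filter gave 18 in naive-like, 37 in Pdcd1-high, 16 in Ly6c2-Cxcr3, 67 in cycling, 4 in CD4 T-like, 60 in regulatory T-like cells and 9 without naive-like ones, with more low-count genes tested, receptor segments among them. The 80% hashtag call gave 2 in Ly6c2-Cxcr3 and 4 in regulatory T-like cells. In Ly6c2-Cxcr3 cells no doublet removal, resolution 0.5 and resolution 1.2 gave 1 each, and the stricter cell filter (1000 genes, 5% mitochondrial UMIs) gave 3. That filter gave 163 in CD4 T-like cells (137 higher, 26 lower), where the class then held Foxp3 at 152 ± 25.1 CPM in LR and 49.6 ± 42.7 in PBS mice (5.21 and 10.7 before), which points to regulatory T cells entering it unevenly.

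With 1 mouse left out, the counts ranged from 1 to 7 in naive-like (7 without PBS mouse 9; 2 without LR mouse 1, LR mouse 4 or PBS mouse 8), 0 to 2 in Pdcd1-high (2 without LR mouse 1, 1 without LR mouse 3), 0 to 2 in Ly6c2-Cxcr3 (2 without LR mouse 4, 1 without LR mouse 1 or PBS mouse 6) and 1 to 5 in regulatory T-like cells (5 without PBS mouse 6, 2 without LR mouse 2 or LR mouse 4). In CD8 T cells without naive-like ones they ranged from 0 to 1, with Gzmb called only without LR mouse 1 and Plac8 without LR mouse 3. Numbers of genes at an unadjusted edgeR p under 0.05 moved too. In CD8 T cells they ranged from 252 (without LR mouse 4) to 1741 (without LR mouse 1), against 626 with all mice. In Pdcd1-high cells they ranged from 183 to 349, against 290. Without naive-like cells they ranged from 237 to 485, against 379.

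Between classes, equal weight per cell gave 572 higher and 3546 lower genes in naive-like cells, 504 lower in Ly6c2-Cxcr3, 826 higher in CD4 T-like and 1090 lower in regulatory T-like cells, and 1 list past camera in Ly6c2-Cxcr3. Without the mouse as a replicate block 692 genes were lower in Ly6c2-Cxcr3, and the block moved no other count of genes or lists by over 1.5 times. Thinning to 1500 UMIs, which leaves fewer genes to test, gave 721 and 907 in naive-like, 844 and 922 in Pdcd1-high, 238 and 320 in Ly6c2-Cxcr3, 991 and 1180 in cycling, 841 and 1179 in CD4 T-like and 817 and 892 in regulatory T-like cells. Against other CD8 T cells only, which leaves out CD4 T-like and regulatory T-like cells, Cd8a turned to −0.56 in naive-like, −0.31 in Ly6c2-Cxcr3 and −0.27 in cycling cells, Crem to 0.63 and Cd8b1 to −0.11 in Pdcd1-high cells. After thinning, list tests turned for homing genes in Pdcd1-high (median 0.16), cytotoxic molecules (0.38) and oxidative phosphorylation (−0.0352) in Ly6c2-Cxcr3 and cytokines in cycling cells (0.90), as did costimulatory receptors in CD4 T-like cells under the stricter filter (−0.0697); the cause was not tested. The odds ratio of Ahr with Ifng excluded 1 within CD8 T cells only (1.41), and that of Prdm1 without class strata (1.51). Thinning left 8301 genes to test in place of 10210 in naive-like and 6377 in place of 9880 in regulatory T-like cells. It also dropped cells under 1500 UMIs and drew the classes again, so this loss cannot be assigned to depth alone.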

Other observations

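The tests of other splits of the mice and of marker lists within classes were chosen only after results were seen. Markers of exhausted CD8 T cells were higher in the Ly6c2-Cxcr3 cluster of LR mice, with a median log2 ratio of 0.55 over 5 measured members (camera adjusted p = 6.55e-06; adjusted p = 0.0453 with an estimated correlation; fry adjusted p = 0.0533). No member passed over all genes and 4 passed adjusted over the list alone. These markers were not left out of clustering and helped to name the classes, so a shift of cell content between clusters is not set apart. In regulatory T-like cells of LR mice, markers of short-lived effector cells had a median of −0.44 (camera adjusted p = 2.64e-05; adjusted p = 0.199 with an estimated correlation), with 3 of 5 lower adjusted over the list alone.

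Among rarer cells, interferon-responsive-like CD8 T cells were 1.80% ± 1.03 of CD8 T cells in LR mice and 0.770% ± 0.0879 in PBS mice (SD, n = 4 each; exact permutation p = 0.143). An Ifng UMI was found in 38.9% of these 54 cells (95% interval 25.9 to 53.1), in 21.7% of NK-like and in 9.09% of regulatory T-like cells. An Ahr UMI was found in 14.6% of myeloid-like cells.

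Regrouping the 8 mice into all 35 splits of 4 against 4 gave no test of chance for genes in CD8 T cells, Pdcd1-high, Ly6c2-Cxcr3, cycling and CD4 T-like cells. The real split called 0 genes there by edgeR, a count that all 35 splits must reach (626, 290, 195, 289 and 179 at an unadjusted p under 0.05; DESeq2 3, 1, 0, 1 and 1). The highest other splits called 2110, 5, 94, 5 and 27. The split with 2110 genes set LR mouse 1 and PBS mice 7, 8 and 9 against the rest, which points to a structure of the mice other than treatment. Those 4 mice had naive-like shares of 54.7% to 90.2% of CD8 T cells, and the other 4 had at most 29.0%. For lists past camera, 18 of 35 splits gave at least the 4 of the real split in CD8 T cells (highest other 6), 12 the 3 in naive-like (5), 11 the 2 in Pdcd1-high (4), 23 the 2 in cycling (6), 5 the 3 in CD4 T-like (4), 10 the 4 in regulatory T-like (7) and 24 the 2 in CD8 T cells without naive-like ones (6). Chance is excluded for none of these 7. In Ly6c2-Cxcr3 the real split had 0 lists, which all 35 splits must reach (highest other 6).

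For the contrasts between classes, the class and the other T cells were exchanged within randomly chosen mice, giving 30 groupings with the real one. The classes were drawn from the same expression values, so the real grouping was bound to call the most genes, and the exchange says nothing about chance for them. Only 1 grouping, the real one, reached its count of genes in each class: 4415 in naive-like cells (highest other 2382), 3459 in Pdcd1-high (598), 1827 in Ly6c2-Cxcr3 (1048), 4979 in cycling (11), 4313 in CD4 T-like (948) and 3499 in regulatory T-like cells (27). The same holds for numbers of lists, since exchanges of few or most mice keep the real contrast. Exchanges of 4 of the 8 mice gave 0 lists in naive-like, at most 3 in Pdcd1-high, Ly6c2-Cxcr3 and regulatory T-like, at most 2 in CD4 T-like and up to 7 in cycling cells. Over all groupings, 8 reached the 7 of naive-like cells (highest other 7), 3 the 6 of Pdcd1-high (6), 2 the 6 of Ly6c2-Cxcr3 (6), 10 the 6 of cycling (7), 6 the 8 of CD4 T-like (8) and 4 the 5 of regulatory T-like cells (6).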
